A study of Drosophila melanogaster with 2 samples.

How the data were processed

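Ovaries of adult female flies that stably express CG17801 with a C-terminal GFP were profiled by ChIP-seq with an anti-GFP antibody, in 2 biological replicates of 1 group numbered 1 and 3, per the labels. The labels give a fragment size range of 200 to 800 bp. The deposited files are peak lists in narrowPeak format on dm6. Per the file headers, which here are the text descriptions deposited with each sample, each replicate list was made from that replicate's alignment and a control file, the pooled list from both alignments and the control, and the IDR list from the 2 replicate lists and the pooled list. The aligner and the peak caller are not given in the sources used here. The signal value of each peak is the authors' own, on a scale the sources do not state, and was used only to rank, describe or filter peaks within a list. The −log10 q-value of each peak, as deposited, was at 1 constant value over the whole IDR list and was not used to rank. The summit offset is, per the deposited format, the distance in bp from the start of the peak, and the summit was taken as the position of each peak. Read totals are unknown from these files, so the depth per sample and the precision it gives cannot be stated. Control and other-factor data were not used here, so binding that any GFP fusion would show in this tissue is not separated from that of CG17801.

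Peak ends lay within the lengths of the Release 6 arms of the reference, and genes came from its Ensembl annotation, with 13945 protein-coding genes and 19607 of their TSSs on X, 2L, 2R, 3L, 3R and the fourth chromosome. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with the random seed 17. Summits within 100 bp counted as matched. A gene was bound when an IDR summit lay within 250 bp of one of its TSSs. Genes with more TSSs thus had more chances to count as bound, and comparisons of bound genes were not matched for TSS number. Summits were placed, in order of priority, in promoter, 5′ UTR, coding exon, 3′ UTR, non-coding exon, intron or intergenic sequence. Overlap and placement were tested against 1000 circular shifts within each arm, and shares carry 95% Wilson intervals that cover sampling of peaks only. Gene lists, arms, non-coding classes and bound against unbound promoters were tested with Fisher's exact test, motifs and k-mers with the exact McNemar test, and p-values were adjusted by Benjamini-Hochberg within each family at 0.05. Pericentric heterochromatin was 2L from 22 Mb, 2R to 5.4 Mb, 3L from 23 Mb, 3R to 4.2 Mb and X from 22 Mb. The tests treat genes and peaks as units, not animals, and the biology rests on 2 replicates.

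The 30 gene lists, the panel of 32 motifs, the main tests and the rule for named genes were set before the data were examined. Named genes are CG17801 and the ZAD list, the 25 genes nearest to the strongest IDR promoter summits found in both replicates, up to 4 bound members of highest signal in each list, and the 10 strongest IDR summits over 250 bp from a TSS. Some genes that this rule names are not reported here. Members of the lists whose symbols differ in the annotation were mapped by hand after a first run of the list tests had been seen, which resolved names only, and 2 members stayed unmatched. The 2 lists of metabolic enzymes, of glycolysis and the citric acid cycle, were chosen after the strongest peaks were seen. Alternatives varied the matching distance, the promoter window, the replicate, the strength of the peaks, the background and the motif windows.

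The procedures were checked on simulated data. With 60% of 6723 summits planted as shared, 60.4% were recovered against a shifted mean of 1.01%. Random summits gave 0 false promoter calls in 40 simulations of 500 summits, with fewer shifts than in the main test. The other placement classes were not simulated. Lists planted with an odds ratio of 4 among 13945 genes were recovered in 87.7% of cases, and 1.74% of other lists were called. A motif planted in 3% of 6723 windows gave an excess of 2.99%, with 0 false calls over the motif panel, and was recovered by the k-mer search, which made 0 false calls of 20. Both false-call checks compared shuffled flank windows of equal base composition. They do not cover false calls where summits and flanks differ in A+T.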

Results

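The series measured where CG17801 sits on the genome of the Drosophila melanogaster ovary. CG17801 is a zinc finger protein with a ZAD domain, a protein interaction domain common in insect zinc finger proteins. Transgenic flies carried the protein fused to GFP at its C-terminus, and chromatin from ovaries of adult females was immunoprecipitated with an antibody against GFP and sequenced (ChIP-seq). The 2 samples form 1 group and are biological replicates numbered 1 and 3. The comparisons that follow are between the replicates, between bound and unbound genes, and between bound sites and other parts of the genome. Each replicate list and the list from both replicates together (the pooled list) held 30000 peaks. The list the authors kept after the irreproducible discovery rate (IDR) procedure held 6723 peaks, and all 6723 were the strongest peaks of the pooled list. Read depth is unknown from peak lists, so no value below carries a counting error from reads. The signal value of a peak is the authors' own value and is used here only to rank or describe peaks within a list. Positions are in dm6 and genes are those of the reference annotation.

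The replicates placed their strongest peaks at largely shared positions. Of the 6723 strongest peaks of replicate 1, 66.5% (4468) had one of the 6723 strongest summits of replicate 3 within 100 bp, with a 95% Wilson interval of 65.3% to 67.6%. In 1000 circular shifts of replicate 3 along each chromosome arm the mean was 1.03% and the highest value 1.61% (one-sided permutation p = 0.001, the smallest that these shifts can give). Against the whole replicate 3 list, 87.5% of the strongest peaks of replicate 1 were matched, and 88.5% of the strongest of replicate 3 were matched in the whole replicate 1 list. Matching fell with rank. Among the 3000 strongest peaks of replicate 1, 94.2% had a partner in replicate 3, while among those ranked 27001 to 30000 the share was 18.2%. Across 15589 matched peaks, Spearman's rho between the ranks was 0.74, which describes peaks and not independent replicates.

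The IDR list was found almost entirely in each replicate. A replicate 1 summit lay within 100 bp of 95.6% of its 6723 summits and a replicate 3 summit within 100 bp of 97.6%, and 93.3% (6271) had one in both. The median distance to the matched summit was 20 bp in replicate 1 and 11 bp in replicate 3. The pooled list shares its reads with both replicates, so this support is not independent of them.

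CG17801-GFP lay mainly at promoters. Of the IDR summits, 57.2% (3843) were within 250 bp of an annotated transcription start site (TSS), a zone that covers 7.49% of the genome and received 7.49% of circularly shifted summits, a ratio of 7.64. Introns held 31.1% of summits against 41.3% of shifted ones, and intergenic sequence 7.30% against 28.3%. Coding exons held 17 summits, 0.253%, against 15.6% of shifted summits. The 3′ untranslated regions (UTRs) held 1.34% against 4.82%. Each of these differences had a two-sided permutation p of 0.002, the smallest that 1000 shifts can give (adjusted permutation p = 0.0028). The 5′ UTRs outside promoters held 1.84% against 1.34% (adjusted permutation p = 0.0117), and that call ended in the stronger 3361 peaks of the list (adjusted permutation p = 0.119) and with a 500 bp promoter zone (adjusted permutation p = 0.188). Exons of non-coding genes held 0.952% against 1.17% and did not pass (adjusted permutation p = 0.124), but were lower with a 500 bp promoter zone (ratio 0.665, adjusted permutation p = 0.0326) and against uniform random positions (ratio 0.747, adjusted permutation p = 0.030). Replicate 1 alone put 57.1% of its strongest peaks at promoters and replicate 3 alone 56.0%. Promoter summits had a median position of -27 bp from the TSS (negative is upstream), with quartiles at -103 and 27.5 bp, and 61.4% of them lay upstream.

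**Figure D1:**
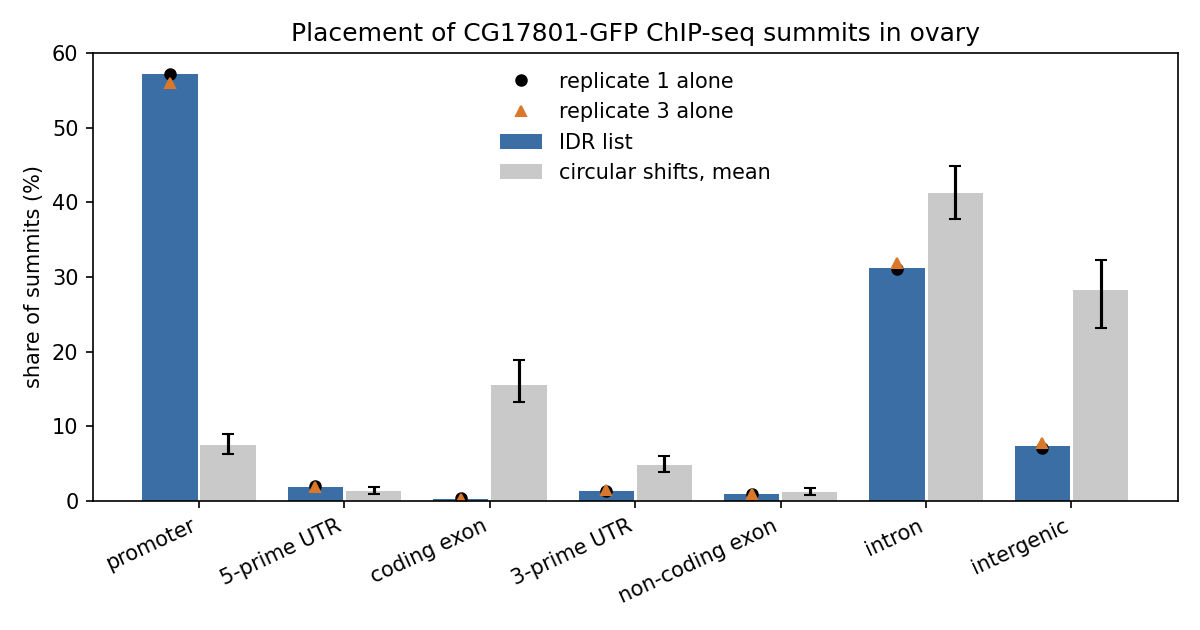
Share of summits (%) in each annotation class. Blue bars are the IDR list, grey bars the mean of 1000 circular shifts with their lowest and highest value as whiskers, and points the same number of strongest peaks from each replicate alone. Promoters hold 57.2% of summits against 7.49% of shifted ones, and coding exons 0.253% against 15.6%.

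The strongest promoter peak was at Ugalt, a UDP-galactose transporter gene (X, 2701124 to 2703852), with its summit at 2703890, at -38 bp from the TSS, and a signal of 3677. It ranked 1 in replicate 1 and 2 in replicate 3. Next came Gapdh2, which encodes a glycolytic dehydrogenase (X, 15868145 to 15869661), with its summit at 15867980 and a signal of 3242, ranked 3 in both replicates. CG11309 on 3L had a signal of 2917 at 21304570, and CG5611 on 3R a signal of 2531 at 27636164. The mitochondrial ribosomal protein genes mRpS10 (3R, summit 15229546) and mRpL41 (2R, summit 15217762) had signals of 2247 and 2141. The chromodomain protein gene Chro, which encodes a protein of chromosome interbands (3L, summit 22878902), had a signal of 1929. Hex-A, the hexokinase gene (X, summit 9585484), had a signal of 1790 with its summit at -191 bp from the TSS. The other genes among the 25 strongest were CG1888, CG18428, CenG1A, CG13390, SLC5A11, CG1635, CG14100, CG18549, gish, Tcs5, aay, Fkbp14, Syp, lawc, Pal1, bbx and Mal-A5, with signals from 2211 down to 1498. Of the 25, lawc had the least similar ranks, 9 in replicate 1 and 75 in replicate 3.

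Several of the strongest peaks lay away from any TSS. The highest signal of the IDR list, 4011, was in an intron of CG11050 (2L, 6612295 to 6613034), with its summit at 6612699, 1012 bp from the nearest TSS. Intronic peaks followed in CG32772 (X, summit 4910391, signal 2980), norpA, which encodes the phospholipase C of phototransduction (X, summit 4324989, signal 2298), CG12769 (2R, summit 8061007, signal 2058) and Tlk (X, summit 3742223, signal 1888). Intergenic peaks lay nearest to DNAlig3 (3R, summit 12403133, signal 2301), CG31668 (2L, summit 2202401, signal 2218) and Hmg-2 (2R, summit 21145853, signal 1925). One peak was in an exon of the non-coding RNA gene lncRNA:Vinr (X, summit 12751324, signal 2159), and one in the 5′ UTR of CLIP-190 (2L, summit 17385364, signal 1726). The CLIP-190 peak ranked 81 in replicate 1 and 14 in replicate 3.

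Of 13945 protein-coding genes on the main arms, 4245 (30.4%) had an IDR summit within 250 bp of a TSS. The strongest peaks of replicate 1 alone reached 4102 genes and those of replicate 3 alone 4151. Of 30 gene lists, 13 were bound more often than other genes, 6 less often, and 11 did not pass Fisher's exact test (two-sided, Benjamini-Hochberg over the 30 lists). Of the 1367 genes in the lists, 44 were in more than 1 list, and neighbouring genes that share a promoter peak both count as bound, so the lists are not independent. The lists were not matched to other genes for the number of TSSs, so part of an odds ratio can come from that number. When only genes with any peak of the pooled list at a TSS served as background, 1 of the 13 lists passed, cytosolic ribosomal proteins, and, of the 6, chemosensory receptors, cuticle proteins and Hox and Polycomb-silenced regulators. Testis-specific genes and neuronal markers did not pass there, and histones were not tested because no histone gene is in that background.

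Of the 30 lists, cytosolic ribosomal protein genes were bound most often and had a promoter peak in 78 of 86 cases (90.7% against 30.1% of other genes, odds ratio 22.7, 95% interval 10.9 to 47.0, adjusted exact p = 2.97e-30). Replicate 1 alone bound 76 and replicate 3 alone 77. The median peak of the 78 lay at percentile 80.3 of signal among all bound genes. Among the strongest, RpL24 had a signal of 1016, RpL32 650 and RpL14 580. Mitochondrial ribosomal protein genes were bound in 43 of 76 cases (odds ratio 3.00, adjusted exact p = 9.67e-06), led by mRpS10, mRpL41, mRpL24 (signal 1020) and mRpL23 (signal 954). That call ended when each summit was given to its nearest TSS only (adjusted exact p = 0.537), with a 100 bp window (adjusted exact p = 0.0943) and in the stronger 3361 peaks of the list (adjusted exact p = 0.0962).

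Genes of transcription and RNA metabolism were also bound more often. General transcription factor and Mediator genes were bound in 48 of 80 cases (odds ratio 3.46, adjusted exact p = 3.31e-07), with Taf5 at a signal of 807, MED30 at 609, Polr2B at 564 and Taf2 at 534. The odds ratio fell to 1.79 with nearest TSS only (adjusted exact p = 0.0349) and to 1.85 in the stronger 3361 peaks (adjusted exact p = 0.0458). Genes of RNA processing and mRNA decay were bound in 23 of 36 cases (odds ratio 4.06, adjusted exact p = 0.000137), led by smg, which encodes a repressor of maternal mRNAs, at a signal of 776, followed by Smg5, Rrp6 and tral. Splicing factor genes were bound in 24 of 40 cases (odds ratio 3.44, adjusted exact p = 0.000549), including U2af50, B52, SC35 and snRNP-U1-C. The splicing call ended with a 100 bp window (adjusted exact p = 0.151) and in the stronger 3361 peaks (adjusted exact p = 0.0824). Signalling genes of the Notch, JAK-STAT, EGFR and BMP pathways were bound in 32 of 49 cases (odds ratio 4.33, adjusted exact p = 2.54e-06), with shn, Krn, neur and aos having the strongest peaks. In the stronger 3361 peaks their odds ratio was 2.37 (adjusted exact p = 0.0257).

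Housekeeping and chromatin groups followed. Autophagy genes were bound in 20 of 30 cases (odds ratio 4.59, adjusted exact p = 0.000214), with Atg2, Atg4b, Atg17 and Vps15 the strongest. Proteasome subunit genes were bound in 21 of 34 cases (odds ratio 3.70, adjusted exact p = 0.000606), among them Rpn3, Prosbeta2, Rpn6 and Rpn13. Replicate 1 alone bound 17 of them (odds ratio 2.41) and replicate 3 alone 25 (odds ratio 6.59). Genes of heterochromatin proteins were bound in 15 of 23 cases (adjusted exact p = 0.00193), with HP1b, HP4 and D1 among the strongest. Genes of insulator and architectural proteins were bound in 14 of 21 cases (odds ratio 4.58, adjusted exact p = 0.00246). Their strongest peaks were at Chro, Cp190, a shared insulator cofactor (signal 1347), Dref (signal 534) and pzg. Genes of oxidative phosphorylation were bound in 35 of 76 cases (95% interval of the odds ratio 1.25 to 3.08, adjusted exact p = 0.00697), led by ND-ASHI, ND-24, ND-MWFE and COX7B. Replication and cell cycle genes were bound in 28 of 59 cases (odds ratio 2.07, adjusted exact p = 0.0104), led by E2f1, SMC2, RnrS and mei-41. The replication and cell cycle call ended with nearest TSS only (adjusted exact p = 0.316), with a 100 bp window (adjusted exact p = 0.395) and in the stronger 3361 peaks (adjusted exact p = 0.228). In those stronger peaks the calls for heterochromatin proteins (adjusted exact p = 0.179), insulator proteins (adjusted exact p = 0.146) and oxidative phosphorylation (adjusted exact p = 0.200) also ended, and with a 100 bp window those for heterochromatin proteins (adjusted exact p = 0.0530) and autophagy (adjusted exact p = 0.0943).

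Among ovary genes, the list for germline stem cells and early oogenesis was bound more often, in 21 of 39 cases (odds ratio 2.67, adjusted exact p = 0.00484), with pum, orb, spn-B and brat the strongest. This call ended with a 100 bp window (adjusted exact p = 0.201) and in the stronger 3361 peaks (adjusted exact p = 0.380). The other ovary lists did not pass. Follicle cell markers were bound in 12 of 24 cases (adjusted exact p = 0.0650), with puc, br, jar and shg the strongest, and passed with a 100 bp window (adjusted exact p = 0.0212) and with nearest TSS only (adjusted exact p = 0.0167). Replicate 3 alone bound 8 of them, and the odds ratio fell from 2.29 to 1.18 (adjusted exact p = 0.709). The piRNA pathway, which silences transposons in the germline, had 15 of 38 genes bound (adjusted exact p = 0.260), with Trf2, tud, papi and spn-E the strongest. Meiotic recombination genes had 12 of 29 bound (adjusted exact p = 0.260), including mus312, Ercc1 and corolla, and maternal axis genes 12 of 30 (adjusted exact p = 0.331), including fs(1)N and spir. Genes of chorion and vitelline membrane had 4 of 24 bound, Vm34Ca, Vml, Vm26Ab and clos (adjusted exact p = 0.230), and were bound less often with a 100 bp window (adjusted exact p = 0.0339). Replicate 3 alone bound 6 of them (odds ratio 0.786 against 0.456, adjusted exact p = 0.823). Yolk protein and lipid uptake genes had 3 of 10 bound, LpR2, apolpp and Yp2 (odds ratio 0.979, adjusted exact p = 1.0). Replicate 1 alone bound 2 of this list (odds ratio 0.600) and replicate 3 alone 4 (odds ratio 1.57). Heat shock and chaperone genes had 10 of 25 bound (adjusted exact p = 0.306), and the median of those 10 lay at percentile 77.4 of signal, with Hsp27 at 1125, Hsp83 at 961, Hsc70-5 at 662 and Hsp26 at 443.

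The 6 lists bound less often were chemosensory receptors, cuticle proteins, replication-dependent histones, Hox and Polycomb-silenced regulators, testis-specific genes and neuronal markers. Chemosensory receptor genes had 1 of 179 bound, Or49b (odds ratio 0.0126, adjusted exact p = 6.10e-26; 1 in replicate 1 alone and 0 in replicate 3 alone), and cuticle protein genes 0 of 107 (adjusted exact p = 1.22e-16). Replication-dependent histone genes had 0 of 111 (adjusted exact p = 3.52e-17), in repeated copies where reads can be hard to place. Hox and other Polycomb-silenced regulators had 5 of 52 bound (odds ratio 0.242, adjusted exact p = 0.00174), with Dll at a signal of 662, then tin, NK7.1 and cad. Replicate 1 alone bound 6 of these (odds ratio 0.312) and replicate 3 alone 3 (odds ratio 0.144). The list of testis-specific genes had 3 of 37 bound, bol, Mst87F and dhd (odds ratio 0.201, adjusted exact p = 0.00387), and neuronal markers 1 of 23, Syx1A (odds ratio 0.104, adjusted exact p = 0.00837). Of these, dhd is a gene of the female germline, and without it, a choice made after the data were seen, 2 of 36 were bound (odds ratio 0.134, adjusted exact p = 0.00105). The testis call ended with a 100 bp window (odds ratio 0.248, adjusted exact p = 0.0644) and the neuronal call in the stronger 3361 peaks (odds ratio 0.103, adjusted exact p = 0.0586). Replicate 1 alone bound 1 gene of the testis list (odds ratio 0.0664) and 0 of the neuronal markers (odds ratio 0.0509). Markers of the muscle sheath (3 of 25 bound, Tm1, mib2 and Mef2, adjusted exact p = 0.0676), of haemocytes (1 of 16, crq, adjusted exact p = 0.0680) and of the fat body (2 of 14, apolpp and Yp2, adjusted exact p = 0.280) did not pass. Muscle sheath and fat body markers passed as bound less often in replicate 1 alone (adjusted exact p = 0.0230 for each), and haemocyte markers when histone genes were left out (adjusted exact p = 0.0479), a choice made after the data were seen. In replicate 1 alone, 2 haemocyte markers were bound, and their odds ratio was 0.342 against 0.152 (adjusted exact p = 0.210).

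The gene of the tagged protein had no promoter peak in any of the 4 lists. CG17801 (3R, 17805679 to 17807085, minus strand) lies in a row of ZAD genes, and the nearest IDR summit, at 17807395, was 310 bp from its TSS in the intergenic gap before Odj. That peak had a signal of 212 and ranked 3126 in replicate 1 and 2337 in replicate 3. Odj (3R, 17807407 to 17809222) had a summit at its TSS with a signal of 254, and CG17806 one 92 bp from its TSS with a signal of 126. Nnk had a peak at its TSS in the pooled list and both replicate lists but not in the IDR list, and CG17803 had none in the 4 lists. Over the whole ZAD list, 10 of 19 genes were bound (odds ratio 2.54, adjusted exact p = 0.0650). The others bound were M1BP (signal 343), Sry-delta (235), mld (170), pita (159), hang (158), Phs (152), dwg (143) and grau (125). ZIPIC, wek, nom and Sry-beta had a TSS peak only below the IDR list, kipf had one in replicate 3 alone, and ouib had none. With each summit given to its nearest TSS only, the ZAD list passed (adjusted exact p = 0.0446), while the odds ratio was 0.912 in the stronger 3361 peaks (adjusted exact p = 1.0) and 1.72 in replicate 3 alone (adjusted exact p = 0.392).

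**Figure D2:**
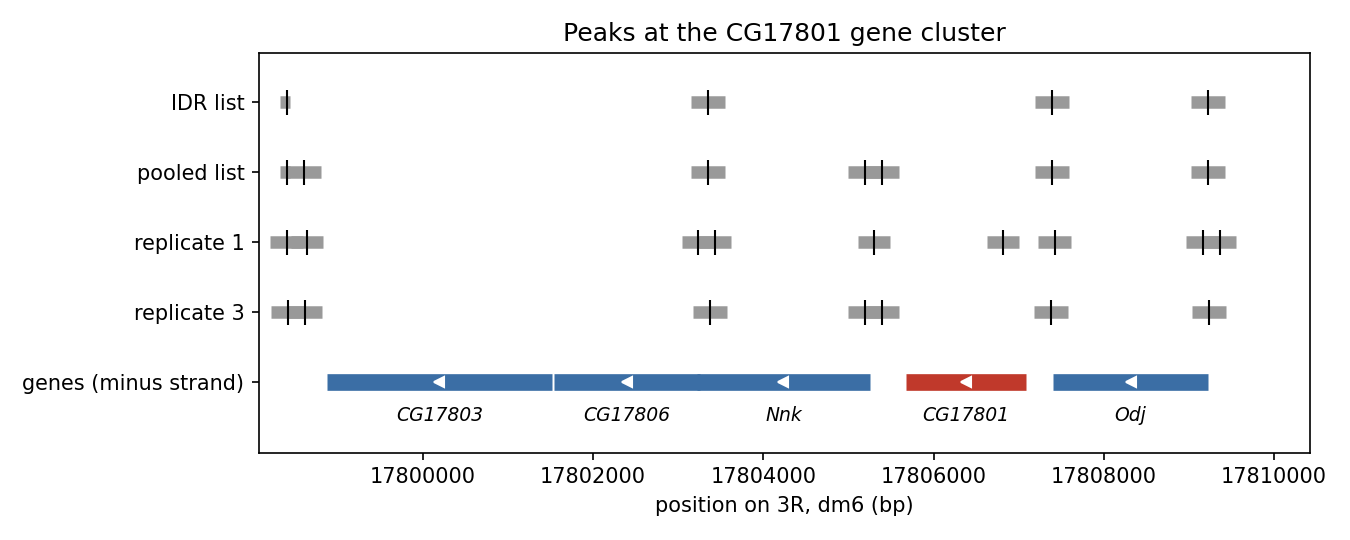
Peaks in the CG17801 gene cluster on 3R (dm6, position in bp). Grey bars are peaks and black ticks their summits in each of the 4 lists, and coloured bars are genes, all on the minus strand, with CG17801 in red. The IDR summit nearest to the CG17801 TSS lies 310 bp from it, at 17807395.

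Promoter binding differed little between arms. On X, 31.6% of 2196 protein-coding genes were bound, on 2R 31.6%, on 3L 29.9%, on 3R 31.3% and on the fourth chromosome 26 of 80. Arm 2L had 27.6% of its genes bound (odds ratio 0.845, 95% interval 0.770 to 0.929, Fisher's adjusted exact p = 0.00154), and no other arm passed with this window. X passed with a 500 bp window (odds ratio 1.14, adjusted exact p = 0.0150) and 2R with a 100 bp window (odds ratio 1.15, adjusted exact p = 0.0218). The 2L call ended in replicate 3 alone (adjusted exact p = 0.0644) and in the stronger 3361 peaks of the list (adjusted exact p = 0.253). Genes in pericentric heterochromatin were bound in 19 of 193 cases, 9.84% against 30.7% (odds ratio 0.246, 95% interval 0.153 to 0.396, adjusted exact p = 5.55e-11), and 31 IDR peaks lay there. The size depends on the settings, with an odds ratio of 0.522 when the limits were moved by 1 Mb and 0.417 with a 100 bp window. How well reads can be placed there, and the copy number of that DNA in the ovary, were not examined. Few peaks there therefore need not mean low binding. Outside promoters, peaks were denser on X, with 36.0 per Mb against 20.7 on the 4 long autosomal arms. The densities were 35.2 and 20.9 for replicate 1 alone and 37.5 and 21.1 for replicate 3 alone.

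Bound genes were often arranged head to head. Of 4245 bound genes, 49.8% had the TSS of another protein-coding gene within 500 bp on the opposite strand, against 17.6% of 9700 unbound genes (odds ratio 4.65, 95% interval 4.29 to 5.04, Fisher's exact test). A summit between such genes counts for both. Genes with more TSSs have more chances both to be bound and to have such a partner, and TSS number was not matched. With each summit given to its nearest TSS only, a choice made after the data were seen, the shares were 38.2% and 23.9% and the odds ratio 1.97 (95% interval 1.81 to 2.14, Fisher's exact p = 1.44e-56).

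Non-coding genes were bound less often than protein-coding ones. Transfer RNA genes were closest, with 71 of 290 bound (24.5% against 30.4%, odds ratio 0.741, Fisher's adjusted exact p = 0.0318), and this call ended with a 500 bp window (adjusted exact p = 0.316). Antisense RNA genes had 50 of 503 bound, small nucleolar RNA genes 15 of 269, long non-coding RNA genes 95 of 1944, microRNA genes 8 of 260, pseudogenes 9 of 268, other non-coding RNA genes 21 of 554 and ribosomal RNA genes 0 of 99. The highest adjusted exact p among these 7 classes was 5.01e-16, that of ribosomal RNA genes. Those genes lie in repeated copies, where reads can be hard to place. Annotated gene starts were used for all classes, and whether each is a promoter was not examined. Protein-coding genes counted as bound at any of their TSSs, and the number of TSSs per gene was not matched between classes. Small nuclear RNA genes had 5 of 32 bound and did not pass (adjusted exact p = 0.0826). The split of non-coding RNA into these classes follows gene symbols and was made after the data were seen.

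Summits differed from their flanks in DRE, Motif 1, the TATA box and other motifs. Of 32 motifs, 13 were more frequent within 50 bp of IDR summits than in windows 500 bp away and 1 was less frequent (exact McNemar test, two-sided, Benjamini-Hochberg over the panel). Flank shares and ratios of the panel are means over the windows on both sides of each summit. The test used a single side per summit, drawn at random. The DNA replication-related element DRE, TATCGATA, the site of DREF, was in 3.05% of 6723 summit windows against 0.431% of flanks (ratio 7.07, adjusted exact p = 3.01e-35). Motif 1, GGTCACACT, the site of M1BP, was in 1.65% against 0.208% (ratio 7.93, adjusted exact p = 1.11e-21). The CGATA core bound by BEAF-32 was in 18.9% against 12.5% (adjusted exact p = 5.03e-25), the TATA box in 7.15% against 4.02% (adjusted exact p = 2.52e-15) and GAGA repeats bound by Trl in 3.42% against 2.16% (adjusted exact p = 0.000489). The GAGA call ended in the stronger 3361 peaks (ratio 1.31, adjusted exact p = 0.424). The initiator was in 10.7% against 8.72% (ratio 1.23, adjusted exact p = 1.77e-05). The CG-rich SP/KLF site was less frequent, 2.08% against 4.04% (adjusted exact p = 1.47e-09). In the strongest 1000 peaks, a split made after the data were seen, the TATA box was the 1 motif that passed as more frequent (ratio 2.75, adjusted exact p = 5.56e-08). DRE (ratio 4.0, adjusted exact p = 0.295) and Motif 1 (ratio 1.0, adjusted exact p = 1.0) did not pass there. All 20 of the 8-mers found on 2L and 2R passed on 3L, 3R and X. They were variants of DRE such as ATCGATAG, parts of Motif 1 such as GGTCACAC, an E-box-containing AACAGCTG, and A+T runs such as AAAATAAA. AAAATAAA was in 8.97% of 4291 windows against 4.96% of flanks (adjusted exact p = 1.25e-12). Summit windows and flanks were not matched for A+T in these tests. Within 50 bp of summits in decile 1 of the IDR list by signal, A+T was 69.2%, against 57.7% over the genome. How far base composition alone accounts for the calls of the TATA box, the CG-rich site and the A+T runs was not tested.

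Compared with windows at the promoters of 9700 unbound genes, 14 of the 32 motifs differed (Fisher's exact test). Bound windows were centred on summits. Each unbound gene gave 1 window at 1 of its TSSs, at a distance drawn at random from those of bound summits. Distances thus match only in distribution. A summit may be centred near a motif where a random position is not, so part of these differences can come from window placement. DRE was in 5.24% of 3699 bound windows against 1.77% (odds ratio 3.07, adjusted exact p = 5.03e-24), Motif 1 in 3.00% against 1.15% (odds ratio 2.65, adjusted exact p = 1.67e-11) and the CGATA core bound by BEAF-32 in 25.2% against 16.6% (odds ratio 1.69, adjusted exact p = 8.69e-27). Here too, the 194 bound windows with DRE are among the 931 with CGATA. The initiator, more frequent at summits than in flanks, was less frequent at bound than at unbound promoters, 12.2% against 15.9% (odds ratio 0.735, adjusted exact p = 2.55e-07). The TATA box did not differ past the threshold, 7.08% against 7.92% (adjusted exact p = 0.202).

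The strongest peaks differed in sequence from the rest. In decile 1 of the IDR list, the peaks of highest signal, A+T made up 69.2% of bases within 50 bp of the summit (SD 9.37 over 673 peaks), against 60.3% (SD 9.61 over 672 peaks) in decile 10 and 57.7% over the genome. DRE was in 1.04% of decile 1 and 3.12% of decile 10, with its highest share, 5.51%, in decile 8. Motif 1 was in 0.149% of decile 1 and 2.83% of decile 10, with its highest share, 3.27%, in decile 7. The share at promoters was 50.5% in decile 1, highest at 62.2% in deciles 4 and 5, and 52.7% in decile 10. Summits found in both replicates fell from 99.3% in decile 1 to 85.4% in decile 10. These values describe the list and carry no test.

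**Figure D3:**
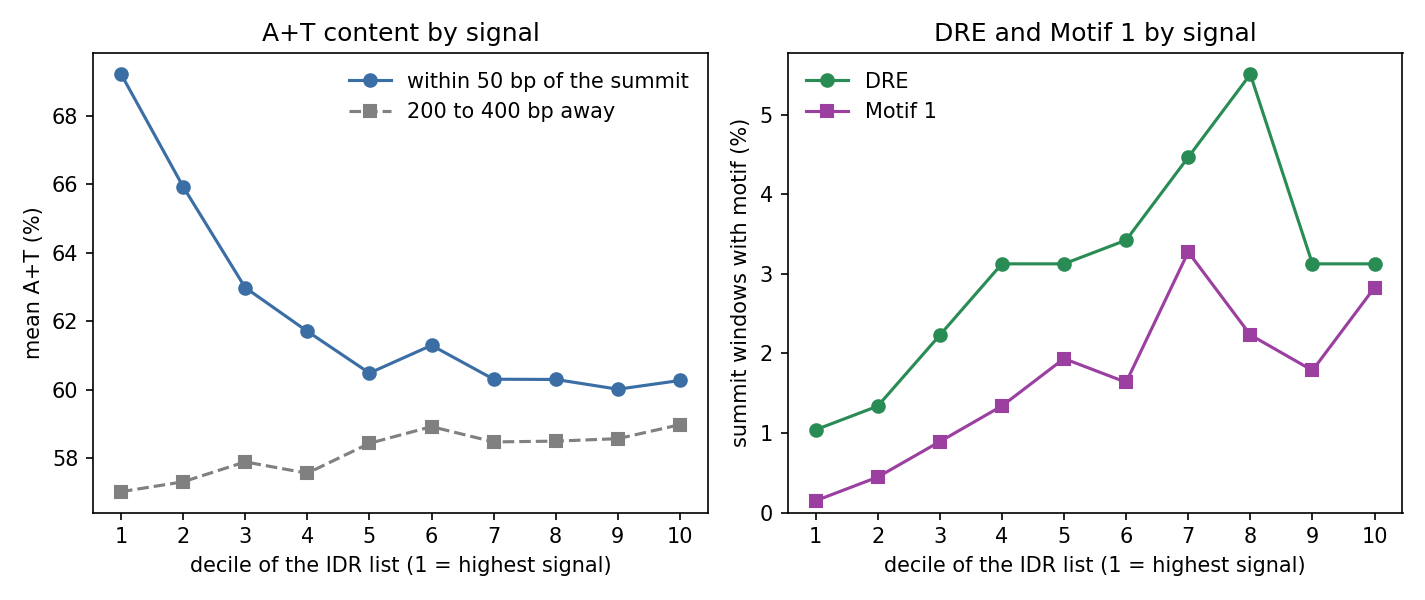
Left, mean A+T (%) within 50 bp of summits (blue) and 200 to 400 bp away (grey) for each decile of the IDR list by signal; right, the share of summit windows (%) with DRE or Motif 1. A+T near the summit runs from 69.2% in decile 1 to 60.3% in decile 10, while DRE is in 1.04% of decile 1 and 3.12% of decile 10, with a maximum of 5.51% in decile 8.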

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

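The authors' threshold left out many pooled-list peaks that both replicates share, a signal in data that the report's main tests do not use. Below the IDR list, 9342 of 23277 pooled-list peaks (40.1%) had a summit within 100 bp in both replicate lists. Circular shifts gave a mean of 501 and at most 700 (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Of the 9342, 32.3% were at promoters, against 21.2% of the peaks not found in both. The pooled list was made from the same reads as the replicate lists, so the excess over shifts is not independent evidence for these sites. No explanation was tested.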

How the results depend on the processing

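Of 762 values recomputed under alternatives, 643 kept their direction and side of the threshold or stayed within their limits. Promoter placement, the low share of bound genes in heterochromatin and head-to-head arrangement did so under all alternatives run, including each replicate alone. Replicate overlap did so under its 5 alternatives of distance, interval and list size, but only in exceeding circular shifts. Its share was not stable, and ran from 50.3% (summits within 50 bp) to 76.5% (interval overlap), against 66.5% in the main test. No alternative bears on how well reads can be placed in heterochromatin. The promoter ratio ran from 4.74 (500 bp) to 11.4 (100 bp), the head-to-head odds ratio fell from 4.65 to 2.20 with a 100 bp window, and the odds ratio in heterochromatin rose from 0.246 to 0.522 with limits moved by 1 Mb. Merging summits within 100 bp removed 0 peaks, so that alternative tests nothing. Moving the heterochromatin limits cannot change the values of the single arms. Both kinds of value are counted among the 643, so that count overstates stability. With summits matched within 50 and 250 bp, the rank correlation was 0.78 and 0.66, support for the IDR list in replicate 1 was 81.4% and 99.7%, and in replicate 3 88.2% and 99.8%. A wider distance matches more summits by construction; why the correlation changed was not tested. Lists bound more often numbered 6 in the stronger part of the IDR list, 8 with a 100 bp window and 1 with genes near any pooled-list peak as background, where lists bound less often numbered 3. The last background holds fewer unbound genes; the cause was otherwise not tested. There the odds ratio of replication and cell cycle genes reversed to 0.916. Motifs less frequent at summits numbered 2 in the stronger part, with windows of 25 or 100 bp and with flanks at 1000 bp. In the strongest 1000 peaks, a split chosen after seeing the data, 1 motif, the TATA box, was more frequent; for the same peaks, 0 of 20 8-mers newly found against windows of matched A+T, also chosen later, passed in 660 windows (0 at an unadjusted p under 0.05, exact McNemar test). These are other 8-mers, so the 20 found in all peaks were not retested there. The motif panel, with the TATA box, was not run against windows of matched A+T. Single ratios reversed for Motif 7 (0.971 in the stronger part, 0.697 in the strongest 1000), GAGA (0.688 in the strongest 1000), Ohler motif 8 (0.40 in the stronger part, 0.0 in the strongest 1000, and from 0.80 to 4.0 without replicate 1 or replicate 3), E2F (1.21 with 100 bp windows) and CA repeats (1.33 with flanks at 1000 bp); the cause was not tested. Unknown read depth limits what weak or missing peaks mean.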

Other observations

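Enzymes of central metabolism were examined after the strongest peaks had been seen. Of 12 glycolytic enzyme genes, 8 had a promoter peak (66.7% against 30.4% of other genes). They were Gapdh2, Hex-A, Eno (2L, summit 1727899, signal 1456), PyK (signal 397), Pgk (268), Ldh (268), Tpi (124) and Ald1 (118). The list was chosen because some of these peaks had been seen, so no test is given, and without the 3 among the 100 strongest peaks 5 of 9 were bound. Of 13 matched citric acid cycle genes, 8 were bound, with Idh3g the strongest (3R, summit 25680730, signal 1133), followed by mAcon1, kdn, Idh3b, Fum1, SdhD, ScsbetaG and Mdh2.

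In the 3 patterns that follow, the tests of base composition, TSS position, matched 8-mers, glycolytic enzymes, single replicates and 1 Mb bins were chosen only after the results were seen. The design holds 1 group, so no biological explanation was tested.

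The strongest peaks had A+T-rich cores, 8.96 percentage points richer in decile 1 than in decile 10. At 200 to 400 bp from the summit the difference was -1.96 points. Library base-composition bias that reached that far out would raise it. By the labels, fragments can be as short as 200 bp and need not reach there, so a bias nearer the summit stays open. Among promoter peaks alone the difference was 10.9 points, so it was not only a contrast of promoter and other peaks. Positions within the 250 bp zone were not matched, so position relative to the TSS stays open. An A+T-rich motif stays open: 0 of 20 8-mers newly found in the strongest 1000 peaks passed against windows of matched A+T in 660 windows, which does not exclude a looser motif.

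Ribosomal protein promoters carried strong peaks, with a median percentile of 80.3. Peak strength may follow gene activity in general, but expression was not analysed here. The medians for oxidative phosphorylation and proteasome genes were 48.7 and 54.7, and that for heat shock and chaperone genes 77.4, so this stays open. Glycolytic enzymes had a median of 80.0, yet 3 of the 8 were among the peaks that prompted the list, and the other 5 had a median of 72.7, which leaves open whether they share the pattern.

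X held 1.74 times as many peaks per Mb outside promoters as the long autosomal arms. An X-wide excess of read coverage would raise promoter peaks too. X promoter peaks had a median percentile of 50.7 among all promoter peaks. Only IDR peaks were ranked, and more coverage could also add weak X peaks, so that median alone cannot decide. The share of genes bound was 31.6% on X and 30.2% on the other arms. Longer introns on X would equalise density per Mb of intron, where the ratio was 1.62 (55.5 against 34.2 peaks per Mb). A single replicate is not the source, since the lower of the 2 replicate ratios was 1.69. Over 22 X bins of 1 Mb the mean was 35.6 peaks (SD 16.8) and over 91 autosomal bins 22.7 (SD 9.51), with a two-sided permutation p of 3e-05 over bins, which are not replicates. Other GFP fusions and the control were not analysed here, so what sets the difference stays open.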
